A study of Rattus norvegicus with 6 samples.

How the data were processed

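RNA from the rostral ventrolateral medulla was measured on 6 Affymetrix Rat 230 2.0 arrays, which read the 3' ends of transcripts. Per the labels, 3 arrays held tissue of 3 spontaneously hypertensive rats (SHR) and 3 held tissue of 3 rats of a strain spelled Wistar-Kyoko there and taken here as Wistar-Kyoto (WKY). Each array therefore stands for 1 animal, and n counts animals. The rats weighed 250 to 350 g and received no treatment, per the labels' protocols. Total RNA was purified on columns, amplified and labelled with biotin. Samples were grouped by the strain in their titles.

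The authors deposited a table of signals on a log2 scale with a detection call for each probe set, and a table of linear signal intensities. MAS5 is the tool named in the submitters' processing notes. Its version is not given in the sources used here. MAS5 summarises the probes of a set as a robust mean of perfect-match minus adjusted mismatch intensities, scales each array to a common level, and calls each set Present, Marginal or Absent. The deposited log2 table equalled the log2 of the deposited linear intensities floored at 1, with a largest difference of 8.2e-06. The trimmed mean of the linear intensities, with 2% removed at each end, was 500.14 on each array, so the arrays had been scaled to each other before deposit. Signals of this kind are noisy near background, and a sequence difference between a strain and the probe can lower a signal without a change in RNA. All values of each sample in these tables were used.

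The tables held 31099 probe sets, of which 57 were array controls and were left out of the tests. Of the others, 19276 carried 1 gene symbol, 1031 carried several and 10735 carried none. Symbols came from the deposited table and were updated through Entrez gene IDs with a RefSeq table of assembly GRCr8. That table held the ID of 18882 of the probe sets with 1 symbol, and 2071 symbols changed. No gene was named from a probe set with several symbols. Coordinates are those of the probe set alignments in the deposited table, on Rnor5.0. No genome sequence was used here, so exons, introns and untranslated regions were not assigned.

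Deposited log2 values were used without further normalization. A probe set was kept if it was called Present on at least 3 of the 6 arrays, which left 20790 probe sets, or 67.0% of those that were not controls. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean signal), with strain as the only factor. P-values were 2-sided and adjusted by the Benjamini-Hochberg method. A probe set or gene was called at an adjusted p under 0.05. For genes, the kept probe set with the highest mean log2 signal over the 6 arrays stood for the gene, and p-values were adjusted over these 10418 genes. A log2 difference is SHR minus WKY throughout. Standard errors are limma's moderated ones.

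The design, gene lists, naming rule and alternatives were fixed before the data were examined. The 32 gene lists covered pathways, receptors and markers of the cell types that the tissue could hold. Each list with at least 5 measured members was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The genes named were the 10 largest rises and the 10 largest falls among called genes whose strains did not overlap and which were Present on at least 2 arrays of each strain. Added to them were up to 5 called genes per direction that were Absent on all arrays of one strain and Present on all arrays of the other, given as a lower bound of the fold. For such a gene the dim strain was set, per array, to the higher of its own signal and the lowest signal called Present. For Rpl39l1, the gene named this way, its own signals were the higher, so this floor did not change its fold. Its WKY signals were called Absent, so the size of the fold is uncertain. The 2 members with the smallest p of each list were also named, called or not, and further called members could be. A gene outside this rule is marked as chosen after its values were seen. Of the genes that the rule allows, 3 are not reported here. Control ratios, Present shares and array medians were compared by an exact 2-sided permutation test, which cannot go below p = 0.1 with 3 arrays against 3.

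The steps were tested on simulated data for this comparison: 10418 genes with the real means and limma's moderated spreads, 200 of them changed, in 5 simulations. Noise was drawn independently for each gene, so genes that vary together were not simulated. The test recovered 51.3% of genes changed by 0.5 on the log2 scale, 88.7% of those changed by 1 and 97.9% of those changed by 2. Of the calls, 7.28% were false. With arrays, the number of animals limits the precision. The median standard error of a gene's log2 difference was 0.12.

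Alternatives were quantile normalization, median centring, pseudocounts of 16 and 64 on the linear intensities, 3 other filters, no variance trend, array weights, the linear table with a pseudocount of 1, the replicate number as a block, each replicate left out in turn, a 1.5-fold minimum, other ways to take a probe set per gene, and other set tests. Terms of the Gene Ontology in the deposited table were tested by a 1-sided hypergeometric test against the 9454 tested genes with any term, over terms of 5 to 500 genes.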

Results

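The rostral ventrolateral medulla is a brainstem region whose neurons drive the sympathetic nerves that set blood pressure. Gene expression in this region was compared between 3 spontaneously hypertensive rats (SHR), an inbred strain that develops high blood pressure, and 3 rats of the Wistar-Kyoto (WKY) strain, the usual normotensive comparison strain. The arrays were alike in overall signal. Between 64.8% and 67.1% of probe sets were called Present, and the array medians lay between 7.43 and 7.47 on the log2 scale. Over kept probe sets, arrays of one strain correlated at 0.97 to 0.98 and arrays of different strains at 0.96 to 0.97, a correlation across probe sets, which are not independent replicates. The lowest value, 0.963, was between SHR replicate 1 and WKY replicate 3.

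The strains differed in a limited set of genes. Transcripts of the type I interferon response were lower in SHR, among them Mx2, Irf7, Oas1a, Rsad2, Isg15 and Usp18. As a list they passed camera at a preset correlation but not with an estimated one (adjusted p = 0.901), and their 12 called members became 1, 0 and 1 without WKY replicate 1, 2 and 3 and 0 without a variance trend. Single genes of varied function differed by 3-fold or more on the probe set used, such as Setd4 and Adpgk (higher in SHR) and Nt5dc1 (lower in SHR). The other kept probe set of Adpgk was also called higher, at 1.40 on the log2 scale. That of Nt5dc1 differed by -0.08 and was not called, and Setd4 had no other. Genes for catecholamine synthesis, angiotensin signalling and amino acid transmission held no called member. Of 20790 probe sets, 192 were called, 109 higher and 83 lower in SHR. Of 10418 genes, 94 were called, 46 higher and 48 lower, and 36 of them differed by at least 2-fold. The 3 animals of one strain all lay above the 3 of the other for 15.3% of genes, where chance gives 10%, and for each of the 94 called genes. The count depends on the animals and on the variance model. It was 34, 27 and 35 without WKY replicate 1, 2 and 3 (22, 21 and 24 higher; 12, 6 and 11 lower), and 31 without a variance trend (21 higher, 10 lower).

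**Figure D1:**
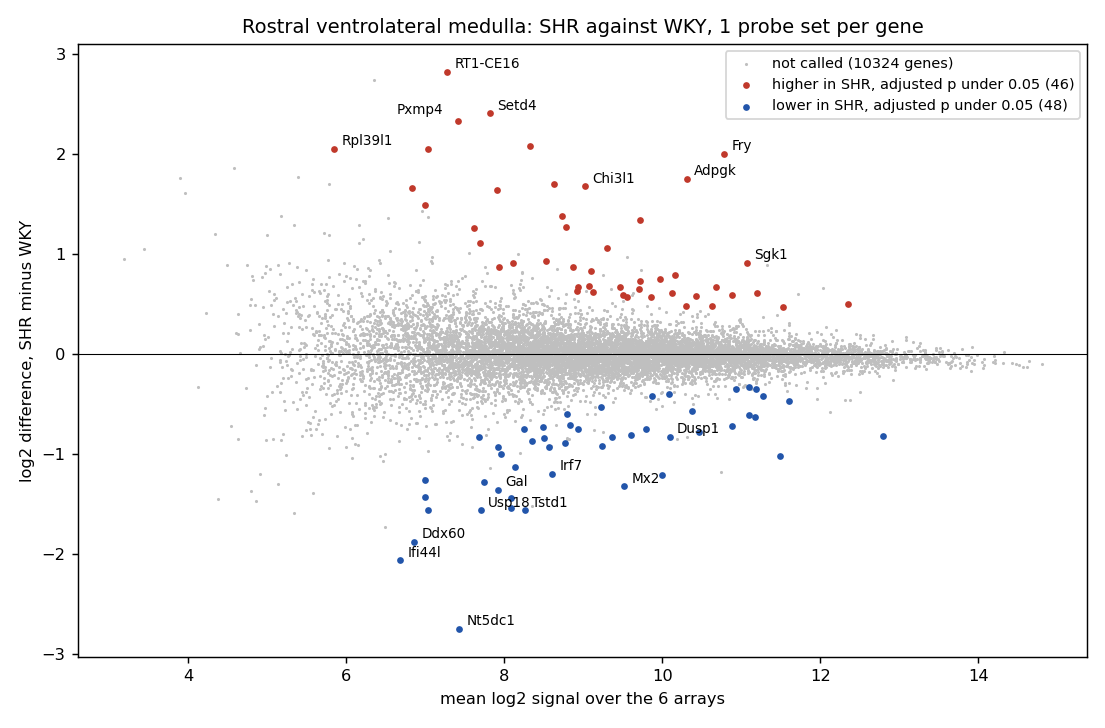
Log2 difference (SHR minus WKY) of each of 10418 genes against its mean log2 signal over the 6 arrays. Coloured points are the 46 genes called higher and the 48 called lower in SHR (limma, adjusted p under 0.05), with some of the named genes labelled.

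Setd4, a SET domain protein, had the largest rise under the naming rule. Its log2 signal was 9.03 ± 0.13 in SHR and 6.62 ± 0.37 in WKY (SD, n = 3 each), a 5.31-fold difference with adjusted p = 0.000336. The probe set lies on chromosome 11 at 37374247 to 37382019 (Rnor5.0). Pxmp4, a peroxisomal membrane protein on chromosome 3 (156464173 to 156464672), was 5.04-fold higher (adjusted p = 0.00157). Adpgk, an ADP-dependent glucokinase on chromosome 8 (63877618 to 63878008), rose from 9.43 ± 0.09 to 11.18 ± 0.14 (SD), or 3.37-fold (adjusted p = 3.08e-05). The transcriptional repressor gene Trps1, the microtubule-related gene Fry, the secreted glycoprotein gene Chi3l1, Mfap3 and the uncharacterised loci RGD1309310 and RGD1566102 were also among the 10 largest rises, at 3.13-fold to 4.16-fold. The call of Mfap3 was lost in 7 settings, without WKY replicate 1, 2 or 3, SHR replicate 1 or 2, a filter or a variance trend (adjusted p between 0.0506 and 0.106), and that of RGD1309310 without WKY replicate 2 (0.133) or a variance trend (0.0629). Second probe sets of Pxmp4, RGD1309310 and Adpgk were also called higher, at 2.96, 1.80 and 1.40 on the log2 scale. Second probe sets of Trps1 and Fry, at 0.71 and 0.05, were not called. Rpl39l1, a ribosomal protein L39-like gene, was Absent on all WKY arrays and Present on all SHR arrays. It differed by 2.05 on the log2 scale (4.15-fold; adjusted p = 0.0288), and by 0.97 with a pseudocount of 64. Its WKY signals lay above the lowest signals called Present, so the floor set for Absent genes did not change this fold. As the gene was not detected in WKY, the size of the difference is uncertain. The call was lost without WKY replicate 1, 2 or 3 (adjusted p = 0.0657, 0.109 and 0.0866) or SHR replicate 1 or 3 (0.0716 and 0.125). It was also lost without a filter (0.0652) or a variance trend (0.0677).

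The largest fall was in Nt5dc1, a 5'-nucleotidase domain gene on chromosome 20 (42893517 to 42893881). Its log2 signal was 6.05 ± 0.22 in SHR and 8.80 ± 0.11 in WKY (SD, n = 3 each), 6.74-fold lower in SHR with adjusted p = 6.88e-05. Its other kept probe set differed by -0.08 and was not called. Tstd1, a thiosulfate sulfurtransferase-like gene on chromosome 13 (94434235 to 94434890), was 2.96-fold lower (adjusted p = 0.00171). Rragd, a Ras-related GTPase of the amino acid sensing branch of mTOR signalling, was 2.69-fold lower (adjusted p = 0.0128). Gal, which encodes the neuropeptide galanin, was 2.57-fold lower, at 7.24 ± 0.41 in SHR and 8.60 ± 0.24 in WKY (SD, n = 3 each; adjusted p = 0.0182). The calls of Rragd and Gal were lost without WKY replicate 1, 2 or 3 (adjusted p between 0.0706 and 0.121), and that of Gal without a variance trend (0.115). The remaining 6 of the 10 largest falls were in Ifi44l, Ddx60, Usp18, Oas1a, Rtp4 and Mx2, all known as interferon-induced genes, at 2.50-fold to 4.18-fold lower. Of the 35 named genes that were called, 12 stayed called under each normalization, pseudocount, filter, variance model and left-out animal that measured them, while other rules for the probe set of a gene were not followed gene by gene. Among the 12 were Setd4, Pxmp4, Fry, Adpgk, Trps1, Chi3l1, RGD1566102, RT1-CE16, Sgk1, Nt5dc1 and Tstd1. Calls of 20, 23 and 21 named genes were lost without WKY replicate 1, 2 and 3, of 7, 9 and 9 without SHR replicate 1, 2 and 3, of 21 without a variance trend and of 9 without a filter.

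Most measured interferon-stimulated genes were lower in SHR. Of 29 measured members of the list, 12 were called and all 12 were lower in SHR. Adjusted over the list alone, 20 were lower and none higher, and 27 of the 29 differences were below 0. Mx2, a dynamin-like GTPase that restricts viruses, fell from 10.18 ± 0.29 in WKY to 8.85 ± 0.38 in SHR (SD, n = 3 each), 2.50-fold (adjusted p = 0.0126), and its second probe set fell by 1.33 on the log2 scale. Irf7, the transcription factor that amplifies interferon production, was 2.29-fold lower (adjusted p = 0.0128). Oas1a, which makes 2'-5' oligoadenylates on sensing double-stranded RNA, was 2.95-fold lower (adjusted p = 0.0151), and Rsad2, an antiviral enzyme also called viperin, 2.19-fold lower (adjusted p = 0.0157). Isg15, a ubiquitin-like modifier, was 2.72-fold lower, although it was Present on 1 of 3 SHR arrays. Usp18, Mx1, Rtp4, Ifi44l and Parp9 were 2.00-fold to 4.18-fold lower, and Rig1 (named Ddx58 in the deposited table), the RNA sensor RIG-I, 1.66-fold lower. The list's mean log2 difference was -0.75 and its median -0.60 (camera, adjusted p = 3.3e-22). With an estimated correlation of 0.42 between its genes the unadjusted p was 0.0331 and the adjusted p = 0.901. Without WKY replicate 1, 2 or 3 the called members numbered 1, 0 and 1, and without a variance trend 0, while 27 of 29 stayed lower in each of these settings (limma; 21 members had an unadjusted p under 0.05 with all animals). Without SHR replicate 1, 2 and 3 the called members numbered 10, 7 and 9, and without a filter 8.

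**Figure D2:**
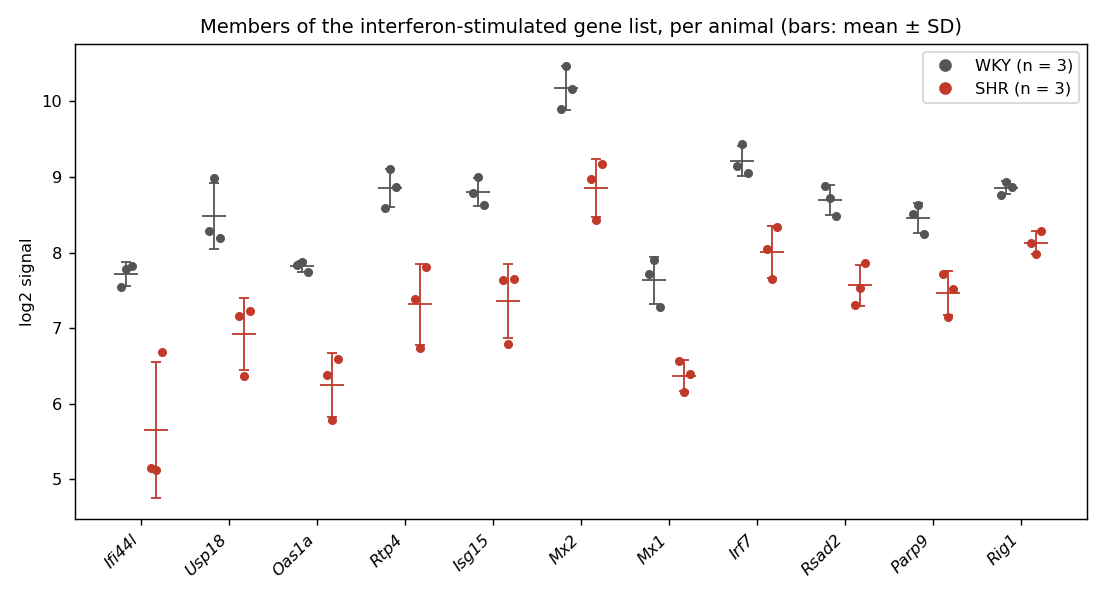
Log2 signal of 11 of the 12 called members of the interferon-stimulated gene list in each animal. Points are animals (3 WKY, grey, and 3 SHR, red), horizontal bars are strain means and error bars are SD. For each gene shown the 3 SHR animals lie below the 3 WKY animals, from 1.66-fold lower for Rig1 to 4.18-fold lower for Ifi44l.

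A further 3 lists passed camera, each with small differences. Oligodendrocyte and myelin markers passed toward lower values in SHR, with 20 of 23 members below 0, a median log2 difference of -0.09 and adjusted p = 0.000139 (adjusted p = 0.901 with an estimated correlation). Limma called no single member, over all genes or adjusted over the list alone, and 9 had an unadjusted p under 0.05. A second probe set of Mobp, a myelin protein gene of the list chosen here after its values were seen, was called lower at -0.99 on the log2 scale (adjusted p over probe sets = 0.000111), against -0.17 for the set used and -0.12 for another, neither called. Enpp6, an oligodendrocyte phosphodiesterase, differed by -0.46 ± 0.14 (SE; adjusted p = 0.246) and Gpr37 by -0.17 ± 0.05 (adjusted p = 0.251). Cholinergic and motor neuron markers passed toward higher values, with all 9 members above 0, a median of 0.24 and adjusted p = 0.00461 (adjusted p = 0.901 with an estimated correlation). Calca and Calcb, which encode calcitonin gene-related peptides, differed by 0.89 ± 0.22 and 0.84 ± 0.22 (SE). Neither was called over all genes (adjusted p = 0.136 and 0.163), and both were called adjusted over the list alone. This list no longer passed without SHR replicate 1 (adjusted p = 0.115), SHR replicate 3 (0.0827) or WKY replicate 2 (0.0658). Cholesterol synthesis genes passed toward lower values, with 23 of 30 members below 0, a median of -0.09 and adjusted p = 0.0141 (adjusted p = 0.901 with an estimated correlation). Sqle, squalene epoxidase, was called at -0.33 ± 0.06 (SE; adjusted p = 0.0427), a call lost when any 1 animal was left out (adjusted p between 0.0664 and 0.225), under quantile normalization (0.0582) and without a filter (0.0531) or a variance trend (0.206). Adjusted over the list alone Lss, lanosterol synthase, was also lower, at -0.38 ± 0.08. The cholesterol list no longer passed without SHR replicate 1 (adjusted p = 0.194) or WKY replicate 2 (0.239), or without a variance trend (0.0625). Camera also called lists between groupings that mix the strains: 7 of the 9 other ways to part the 6 arrays into 3 and 3 gave 4 lists or more, and up to 12.

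**Figure D3:**
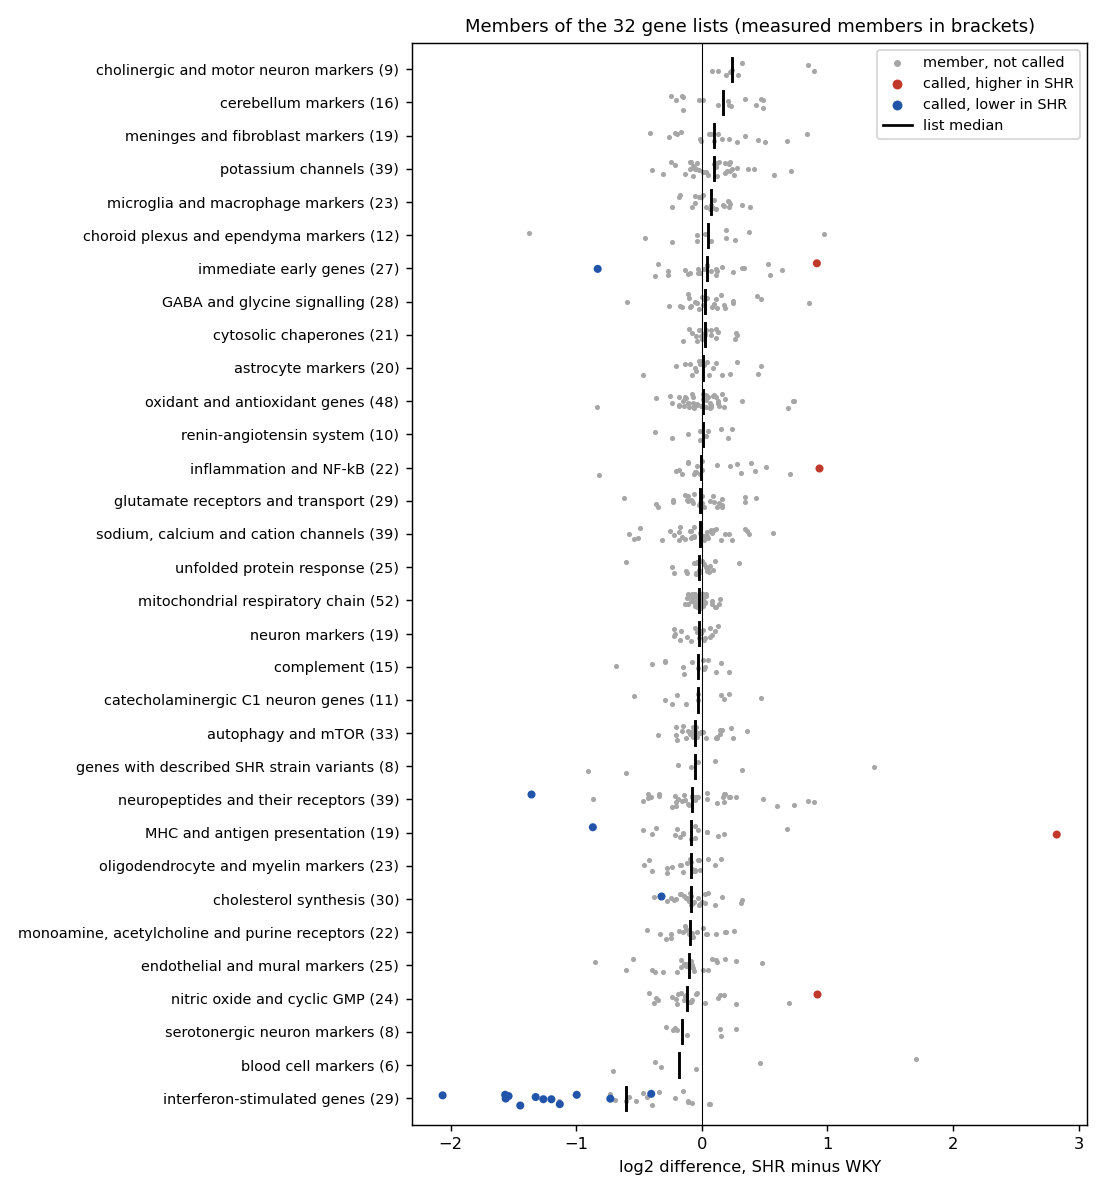
Log2 difference (SHR minus WKY) of each measured member of the 32 gene lists, ordered by list median (black bar). Grey points were not called, and coloured points were called higher (red) or lower (blue) in SHR. The interferon-stimulated list has the lowest median, -0.60, and holds 12 called members.

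Few genes tied to the neurons of this region were called. Among 11 catecholaminergic C1 neuron genes limma called none, and 2 had an unadjusted p under 0.05: Maob at -0.23 ± 0.08 and Maoa at 0.22 ± 0.10 (SE; adjusted p = 0.373 and 0.508), enzymes that degrade monoamines. Dbh and Pnmt, genes of catecholamine synthesis chosen after their values were seen, differed by -0.54 ± 0.25 and -0.29 ± 0.20 (SE). Neither was called (limma, adjusted p = 0.546 and 0.724), and of the 11 genes 7 were lower and 4 higher. With errors of this size, moderate differences could be missed. Tyrosine hydroxylase, Th, chosen after its values were seen, ranged from 9.55 to 10.99 among SHR animals and from 8.84 to 11.64 among WKY animals, so a strain difference was not detectable against that spread. None of 10 measured renin-angiotensin genes was called or had an unadjusted p under 0.05. Agt, angiotensinogen, differed by 0.24 ± 0.11 (adjusted p = 0.549) and Mme by -0.37 ± 0.32 (adjusted p = 0.787). Limma called none of 29 glutamate genes, 28 GABA and glycine genes, or 22 receptors for monoamines, acetylcholine and purines, with 1, 2 and 0 members at an unadjusted p under 0.05. The smallest p-values in these lists belonged to Grm4 (0.34 ± 0.14; SE) and Gria3 (0.16 ± 0.08), the glycine receptor gene Glra1 (0.85 ± 0.26) and the GABA transporter gene Slc6a11 (0.47 ± 0.21), and Nisch (-0.12 ± 0.06) and Adra2a (-0.34 ± 0.17), at adjusted p between 0.268 and 0.607. Among 39 neuropeptide and receptor genes 1 was called, Gal, and adjusted over the list alone Calca and Calcb were higher beside it. No member was called among 39 potassium channel genes (4 with an unadjusted p under 0.05) or 39 sodium, calcium and cation channel genes (3). Kcnip4 (-0.31 ± 0.10), Kcnab1 (0.24 ± 0.09), Scn8a (0.57 ± 0.20) and Itpr1 (0.35 ± 0.14) had the smallest p-values there. Another Glra1 probe set differed by 0.04. Other sets of Nisch, at 0.12 and 0.06, and of Kcnab1, at -0.16, had the opposite sign to the set used. None of these was called.

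Of the lists of stress and immune genes outside the interferon list, 5 (immediate early, inflammation, nitric oxide, antigen presentation and oxidant genes) passed fry for either direction (adjusted p between 0.00146 and 0.0109) and none passed camera. Sgk1, a kinase induced by glucocorticoids and mineralocorticoids, rose from 10.61 ± 0.08 in WKY to 11.53 ± 0.05 in SHR (SD, n = 3 each), 1.89-fold (adjusted p = 0.00014), on chromosome 1. Dusp1, a phosphatase of MAP kinases, was 1.78-fold lower (adjusted p = 0.0128), a call lost without WKY replicate 2 or 3 (0.105 and 0.0779), SHR replicate 3 (0.0521) or a variance trend (0.125). Sgk1 and Dusp1 were the called members of 27 immediate early genes, and adjusted over the list alone 2 were higher and 1 lower. The cytokine gene Il18, in the list of 22 inflammation genes, was 1.91-fold higher (adjusted p = 0.0182), a call lost without WKY replicate 1, 2 or 3 (0.107, 0.12 and 0.0596), SHR replicate 3 (0.0748) or a variance trend (0.103). Il6st differed by 0.28 ± 0.09 (SE; adjusted p = 0.302) with its 3 other probe sets between -0.12 and -0.24. Pde10a, a cyclic nucleotide phosphodiesterase, was 1.88-fold higher among 24 nitric oxide and cyclic GMP genes (adjusted p = 0.0491), a call lost under median centring (0.0516) and quantile normalization (0.0659), without SHR replicate 1 or 2 (0.106 and 0.134) and without WKY replicate 1, 2 or 3 (0.208, 0.229 and 0.0761), and without a filter (0.084) or a variance trend (0.137). Nos1ap differed by 0.69 ± 0.19 (adjusted p = 0.207). Il18 and Pde10a were also the calls adjusted over the list alone. Of 19 genes of antigen presentation, 2 class I genes were called, over all genes and adjusted over the list alone: RT1-CE16 was 7.08-fold higher (adjusted p = 0.000581; Present on 1 of 3 WKY arrays) and RT1-S3 1.83-fold lower (adjusted p = 0.0434), a call lost when any 1 animal was left out (adjusted p between 0.0674 and 0.214) and without a filter (0.073) or a variance trend (0.137). Class I genes are near-identical copies and the RT1-CE16 probe set is of the kind that can bind related transcripts, so these values are uncertain as to the gene. Among 48 oxidant and antioxidant genes none was called (7 with an unadjusted p under 0.05), and adjusted over the list alone Hmox1, heme oxygenase, was higher at 0.68 ± 0.16 and Txnip lower at -0.84 ± 0.20.

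The other functional lists held no called gene in limma. Unadjusted p fell under 0.05 for 1 of 15 complement genes (C1r, -0.68 ± 0.21; SE), and C5ar1 differed by -0.39 ± 0.18. It did so for 2 of 25 unfolded protein response genes (Atf6, -0.60 ± 0.19, and Pdia4, -0.23 ± 0.08), and for 0 of 21 cytosolic chaperones, where Stip1 differed by -0.15 ± 0.09 and Hspe1 by -0.08 ± 0.05. Of 33 autophagy and mTOR genes 3 did so, led by Prkag1 (0.24 ± 0.07) and Gabarapl1 (0.14 ± 0.06). A second Gabarapl1 probe set was called in the opposite direction, at -0.62. Of 52 respiratory chain genes 0 did so, with Ndufa5 at -0.13 ± 0.06 and Cox7b at -0.10 ± 0.05. Among 8 genes with described SHR strain variants, 4 did so. Ephx2, soluble epoxide hydrolase, differed by 1.37 ± 0.37 (adjusted p = 0.182, called adjusted over the list alone), with 7.72 ± 0.87 in SHR and 6.36 ± 0.02 in WKY (SD, n = 3 each), and Endog by -0.90 ± 0.32. The median, mean and camera direction differed in sign for 7 lists, none of which passed camera: the renin-angiotensin, glutamate, inflammation, antigen presentation, strain variant, choroid plexus and blood cell lists.

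Apart from the oligodendrocyte and cholinergic lists, markers of cell types did not pass camera and limma called none of their members. Members with an unadjusted p under 0.05 numbered 2 of 19 for neurons, 0 of 8 for serotonergic neurons, 5 of 20 for astrocytes, 0 of 23 for microglia and 3 of 25 for endothelial and mural cells. They numbered 0 of 12 for choroid plexus and ependyma, 1 of 19 for meninges, 2 of 16 for cerebellum and 4 of 6 for blood cells. Microglia markers had a median log2 difference of 0.07 beside the fall of the interferon-stimulated list. The synaptic vesicle gene Syp differed by -0.21 ± 0.08 (SE), Ina by -0.17 ± 0.07, Htr1a by -0.28 ± 0.26, Gata3 by 0.14 ± 0.20, Acsbg1 by 0.23 ± 0.07 and Slc4a4 by 0.45 ± 0.17. Another Ina probe set, at 0.05, had the opposite sign and was not called. Aif1 and Gpr34, of microglia, differed by -0.17 ± 0.11 and 0.32 ± 0.22. Vwf, the von Willebrand factor of endothelium, was lower when adjusted over the list alone, at -0.85 ± 0.19 (adjusted p over all genes = 0.1), and Abcg2 differed by 0.48 ± 0.15. Kcne2 (-1.38 ± 0.73), Folr1 (-0.46 ± 0.28), Igfbp2 (0.34 ± 0.15), Col4a1 (-0.21 ± 0.13) and Reln (-0.25 ± 0.09) had the smallest p-values of the tissues that border the region, with Itpr1 again for cerebellum. Kcne2 was Present on 1 of 3 SHR and 2 of 3 WKY arrays, so its difference is a value near background. Among blood cell genes, 1 was higher and 2 were lower adjusted over the list alone. The 1 higher was S100a9, a neutrophil protein, Present on the 3 SHR arrays and Absent on the 3 WKY arrays (adjusted p over all genes = 0.0662), so the size of its difference is not given.

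Measures of RNA and array quality were compared between the strains by an exact permutation test, which cannot go below p = 0.1 with 3 arrays against 3. The 3' minus 5' log2 difference of the beta-actin control was 1.44 ± 0.23 in SHR and 1.33 ± 0.05 in WKY (SD, n = 3 each; exact permutation p = 0.7, 2-sided), with the highest value, 1.69, in SHR replicate 1. For Gapdh the values were 0.28 ± 0.03 and 0.26 ± 0.02 (exact permutation p = 0.4). Present shares were 66.4% ± 0.81 and 65.5% ± 0.53 (exact permutation p = 0.3). Array medians were 7.46 ± 0.01 in SHR and 7.44 ± 0.01 in WKY, without overlap (exact permutation p = 0.1). The median log2 difference over all genes was -0.0045.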

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

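Called probe sets, called genes and the 4 lists past camera kept their size, within 1.5 times, under both normalizations, both pseudocounts, the 3 filters, array weights and the other deposited table. Between 73 and 100 genes were called there, 70 to 94 of them shared with the 94. Other rules for the probe set of a gene gave 77 to 94 genes, and a 1.5-fold minimum gave 79. Without a variance trend 63 probe sets and 31 genes were called, all 31 among the 94, and the cholesterol list's mean of -0.0727 had adjusted p = 0.0625. The cause was not tested. Leaving out 1 animal gave 78 to 205 probe sets, 27 to 90 genes and 2 to 6 lists. The low ends came from leaving out WKY animals (81, 81 and 78 probe sets), while fits of the same size without an SHR animal gave 205, 137 and 201. In limma's array weights, WKY arrays had 1.19, 1.26 and 1.14 and SHR arrays 0.549, 0.974 and 1.1. WKY arrays correlated with each other at 0.977 to 0.98 and SHR arrays at 0.97 to 0.977. Whether the larger spread of the SHR arrays accounts for the lower counts was not tested. At camera's preset correlation, the interferon-stimulated list passed in each of the 6 fits that left out 1 animal, which share animals (adjusted p between 1.31e-23 and 6.45e-17). The oligodendrocyte list did likewise (5.02e-05 to 0.0157). Mean log2 differences ranged from -0.859 to -0.608 for the interferon list and from -0.161 to -0.0951 for the oligodendrocyte list. They ranged from 0.246 to 0.553 for cholinergic markers and from -0.103 to -0.0343 for cholesterol synthesis.

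Camera with an estimated correlation, and fry for one direction, called 0 lists. With an estimated correlation 1 list, and in fry 2 lists, had an unadjusted p under 0.05. The means of the 4 lists, -0.747, -0.129, 0.356 and -0.0727 (interferon, oligodendrocyte, cholinergic and cholesterol), do not change with the set test. Their adjusted p was 0.901 with an estimated correlation for each, and 0.25, 0.677, 0.914 and 0.914 in fry. An estimated correlation allows more than the preset one for genes of a list that vary together, and fry does not compare a list with other genes. Fry for either direction called 9 lists, 3 of the 4 among them, and left out the cholinergic list (adjusted p = 0.606).

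The replicate number as a block gave 196 probe sets, 110 genes and 4 lists, with 87 of the 94 genes shared. Calls of 3 named genes, Pde10a (adjusted p = 0.0705) and Sqle (0.0539) among them, were lost there. The numbers gave little sign of pairing, without settling it: deviations from the strain means correlated at 0.077, -0.01 and 0.066 for same-numbered animals. SHR replicates 1 and 3 correlated best with the WKY animal of their own number, and SHR replicate 2 did not. Of the named genes, Htr1a alone turned its direction, in fits that left out 1 animal. Its log2 difference ranged from -0.488 to 0.023 (0.023 without SHR replicate 1) and was not called. Background limits the dim genes: the pseudocount of 64 took Rpl39l1 from 2.05 to 0.97.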

Other observations

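The tests of cell type and single animals for the interferon-stimulated genes, the enrichment of terms, and the test of the glucocorticoid-responsive genes were chosen after the results were seen.

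Beyond the fixed lists, terms of the Gene Ontology were tested for enrichment among the called genes. Of 3566 terms, 3 passed among genes lower in SHR and 0 among genes higher. The 3 were defense response to virus (6 of 46 genes called lower: Ddx60, Isg15, Mx1, Mx2, Oas1a and Rsad2; hypergeometric adjusted p = 0.000207), response to virus (5 of 50; adjusted p = 0.00559) and negative regulation of viral genome replication (3 of 14; adjusted p = 0.0393), which share genes with the interferon list. Some called genes outside the naming rule were chosen here after their values were seen. Septin5, a septin of presynaptic terminals, was 2.54-fold higher in SHR (limma, adjusted p = 0.000201). Vamp2, a synaptic vesicle fusion protein, was 1.33-fold lower (adjusted p = 0.0128), Thy1, a neuronal surface protein, 1.77-fold lower (adjusted p = 0.00212), and Cyfip2, a regulator of actin in neurons, 1.39-fold lower (adjusted p = 0.0126). Eif3c, a translation initiation factor subunit, was 2.03-fold lower (adjusted p = 3.08e-05). Second probe sets of Thy1, Cyfip2 and Eif3c, at -0.18, 0.21 and -0.41 on the log2 scale, were not called, and that of Cyfip2 had the opposite sign. Each of these separated the 6 animals by strain. Ube2l6 and Lgals9, interferon-induced genes outside the list, were 1.77-fold and 1.79-fold lower (adjusted p = 0.039 and 0.0253).

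The fall of interferon-stimulated genes in SHR was weighed against 3 technical explanations. A smaller share of microglia would have to lower microglia markers by about as much, but their median log2 difference was 0.07, with quartiles of -0.04 and 0.19, against -1.29 for the called members. Leaving out any 1 animal left the list's mean at -0.608 or further from 0. However, single calls fell to 0 or 1 without a WKY animal, and to 10, 7 and 9 without SHR replicate 1, 2 and 3. Sequence variants under single probe sets stay open: the test set in advance needed 5 other probe sets of the called members, and the 3 at hand had a median log2 difference of -0.35. A comparison of directions tried later was dropped, since it restated the pattern. A strain difference in interferon signalling, or an exposure such as an infection shared by the animals of a strain, may also account for the fall, and these were not tested, since housing and strain cannot be separated with the labels.

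The differences in single genes outside that list may in part come from sequence variants under the probes, and this remains open. For 26 of the 82 such genes another kept probe set was at hand, and the others differed in the called direction by a median of 0.44 on the log2 scale, against 0.89 for the chosen ones. In 18 genes the others had the called sign and in 8 the opposite, a mixture that does not decide between a variant and a change in RNA. Variants in linked stretches of the genome could also place called genes near each other: 16 of 81 such genes had another within 1 Mb, against a median of 9 in 10000 random draws (permutation p = 0.07), a p that excludes nothing, although by the bound of 0.05 set in advance it would have counted against linked stretches. Among them were RT1-CE16 and RT1-EC2, which moved in opposite directions at overlapping positions on chromosome 20. Within 5 Mb, 31 of the 81 had another such gene, against a median of 26 in the random draws (permutation p = 0.23).

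The rise of Sgk1, and of Ddit4 (0.59 on the log2 scale, adjusted p = 0.0303), both known as glucocorticoid-responsive, raised the hypothesis of higher corticosteroid receptor activity in SHR. In a list of 29 other such genes, without Sgk1, Ddit4, Gpd1 and Dusp1, 24 were higher in SHR and none was called by limma. The median log2 difference was 0.19, above 100% of 10000 random lists matched on mean signal, but random lists do not vary together as these genes do. The other splits of the 6 animals gave medians of up to 0.17 in size, and camera gave p = 2.1e-06 at the preset correlation and p = 0.16 with an estimated correlation of 0.31. The comparisons with the splits and with camera were added as requirements after the random lists alone had met the first bound, and the values of some members, Tsc22d3 and Fkbp5, had been seen when the list was written. The hypothesis stays open. Of the genes left out of the list, Gpd1 was called higher in SHR (0.59 on the log2 scale, adjusted p = 0.0182), with a second probe set at 2.27 that was not called, and Dusp1, which glucocorticoids are known to induce, was called lower.

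The other splits of the 6 animals bear on the counts in the same way, with no share under 0.05 within reach of 10 splits. The real split called 192 probe sets and 94 genes (1 of 10 splits as large for each), and the highest of the others called 0 of either. The interferon list's mean was 0.747 in size in the real split (1 of 10 as large) and 0.442 in the highest other. Each other split mixes the strains, so a strain difference raises its spread and enters its means in part. The calls and means of the other splits therefore do not show what chance alone would give. For gene lists past camera the real split gave 4 and the highest other 12, and 8 of the 10 splits gave 4 or more. The count of lists at the preset correlation therefore does not set the strains apart from other groupings.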
